A study of Mus musculus with 10 samples.

How the data were processed

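Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on primary cortical neurons of C57BL/6J mice on day 6 in vitro. After a night in 3% serum the cultures received either no treatment or, for 45 min, KCl at 50 mM, per the labels. The antibodies were directed against Gtf3c1 (the largest subunit of the RNA polymerase III initiation factor TFIIIC), Rpc155 (the largest subunit of RNA polymerase III), H3K4me1 and H3K27ac. There were 4 antibodies and 2 conditions, giving 8 peak lists, 1 for each antibody and condition. Total chromatin input served as the control, per the series design text, and the input libraries were not analysed here. The design text states 3 biological replicates per condition. Whether the replicates were pooled before peak calling is not given in the sources used here.

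Reads were aligned with Bowtie2 to GRCm38/mm10 and peaks were called with MACS2, per the submitters' processing notes; the versions are not given in the sources used here. Each deposited list holds a position and a summit per region. The deposited fold enrichment is the ratio of the summit to the local background. The deposited −log10 p and −log10 q are the peak caller's values for the region. The deposited score equals 10 times the −log10 q, rounded down. The highest q lay just under 0.05 in each list (lowest −log10 q of 1.30 to 1.31) except the KCl list of Rpc155, which ended at 1.46. A q of 0.05 was taken as the authors' threshold. These values are the authors', and they were used to describe, rank or filter regions within a list. Fold enrichment and p were also set side by side between the untreated and KCl lists. They were not adjusted for differences between libraries. No region overlapped another of its list, so none was merged. Regions on chromosomes 1 to 19, X and Y were used. The number of columns of per-sample values left unused was 0.

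The lists hold no read counts, so the depth of the libraries is not known from them directly. A background level was worked back from the spacing of the fold enrichment values, taking each as (pileup + 1) / (background + 1) with a whole number of fragments at the summit. Between 66.3% and 86.4% of regions per list gave a whole pileup within 0.01 fragments. The background was 4.58 fragments per position in the untreated and 4.57 in the KCl list of Gtf3c1. It was 4.89 and 4.51 for Rpc155, 4.63 and 4.66 for H3K4me1, and 6.88 and 6.40 for H3K27ac. The background scales with the reads times the fragment length, so it bounds depth only together with fragment length.

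Genes came from a RefSeq table of the same build, with 49943 genes on these chromosomes, 21887 of them protein-coding, 408 nuclear tRNA genes and 53 5S rRNA genes. Strand, exons and sequence were not used here. For this reason the planned distance to a transcription start site was replaced by the distance to the nearer end of a gene, so that 5′ and 3′ ends count alike. Exons and introns were not told apart. The planned search for B1 and B2 SINE sequences was not run. Of 197 symbols on the gene lists, 195 were found.

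Regions were called shared or overlapping when they had at least 1 bp in common. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Overlap shares were set beside the mean of 100 random placements of the same regions on the same chromosome. An active distal enhancer was defined as an H3K4me1 region that overlapped an H3K27ac region and lay more than 1 kb from any gene end. RNA polymerase III genes were counted when a region overlapped the gene or its 200 bp flanks. Listed genes were counted when a region lay within 5 kb of a gene end, or within 1 kb for the cell type markers in H3K27ac. For each list, the number of genes with a region in the KCl list alone minus the number in the untreated list alone was ranked among 10000 random protein-coding lists matched on deciles of gene length. This percentile describes the lists; it is not a test across replicates. With 1 list per antibody and condition no difference between conditions has a replicate check, and no p-value is given.

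Gene lists fixed before the data were examined covered immediate-early and delayed activity-regulated genes, synaptic genes, glutamatergic and GABAergic neurons, astrocytes, the oligodendrocyte lineage, microglia, endothelium, neural progenitors, non-neural tissue, the RNA polymerase III machinery, RNA polymerase III transcripts and housekeeping genes. Named genes were the members of these lists, the 10 regions with the highest −log10 q of each list, and the 10 such regions found in 1 condition alone, each named by the gene with the nearest end or, where that was a predicted model, by the gene that held the summit. Some named regions and genes are not reported. Predicted gene models were left out of the naming.

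Alternatives fixed beforehand were a q of 1e-05 or lower, an overlap of at least 50% of the shorter region, equal list lengths (the strongest regions of the longer list), joining regions under 1 kb apart, placements 10 to 100 kb away, a distal limit of 5 kb, the whole region in place of its summit, and windows of 50 kb for activity-regulated genes and 5 kb for markers. Added after the data were seen were the same p in both lists of an antibody, a fold enrichment of at least 6, and random gene lists matched also on H3K27ac. The share of gene length covered by regions, the strongest 500 regions, Gtf3c1 at tRNA genes with strong Rpc155 regions, chromosome X and the fold enrichment classes of Rpc155 regions were also looked at only after the lists had been seen.

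Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap, distance, random-list and background steps were tested on simulated data. For shared regions, 64988 simulated regions with 61.5% planted overlaps gave back 61.5%. A planted net gain of 5 among the 32 immediate-early genes ranked at percentile 100. In this simulation the 32 genes lost no region while other genes did, so the rank does not isolate the planted gain. Of 200 random lists of 32 genes with no planted gain, 1.0% reached the 97.5th percentile. A planted background of 4.7 fragments per position was recovered as 4.7 from 3473 simulated regions.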

Results

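The data describe where TFIIIC and RNA polymerase III sat on chromatin of mouse cortical neurons, and where the enhancer-associated histone marks H3K4me1 and H3K27ac lay, before and 45 min after depolarization with 50 mM KCl. KCl opens voltage-gated calcium channels and induces immediate-early genes. Each antibody gave 1 peak list per condition, so all differences below are between lists and have no replicate check. Positions are 1-based on GRCm38/mm10.

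The first comparison asked how many regions each antibody occupied without and with KCl. Gtf3c1, the DNA-binding TFIIIC subunit, was listed at 66622 regions in untreated neurons and at 58090 with KCl. Rpc155, the catalytic subunit of RNA polymerase III, was listed at 12531 and 4251 regions, 2.95 times fewer with KCl. H3K4me1, a mark of enhancers, covered 177 Mb in 192225 regions and 183 Mb in 193683 regions. H3K27ac, a mark of active enhancers and promoters, covered 71.1 Mb in 65486 regions and 71.9 Mb in 58124 regions. The shorter Rpc155 list held nearly as many strong regions as the longer: 588 untreated and 584 KCl regions had a fold enrichment of at least 6, and 265 and 343 of at least 10. For H3K27ac, 1223 untreated and 4496 KCl regions reached a fold enrichment of 10.

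Of the untreated regions, 81.7% (95% interval 81.5 to 81.8) overlapped a KCl region for H3K4me1 and 62.7% (62.3 to 63.0) for H3K27ac. The share was 45.6% (45.2 to 46.0) for Gtf3c1 and 17.6% (16.9 to 18.3) for Rpc155. In the other direction, 51.9% of the KCl regions of Rpc155 overlapped an untreated region, leaving 2044 in the KCl list alone against 10328 in the untreated list alone. The Rpc155 share was 32.6% with equal numbers of regions and 65.1% among regions with a fold enrichment of at least 6.

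**Figure D1:**
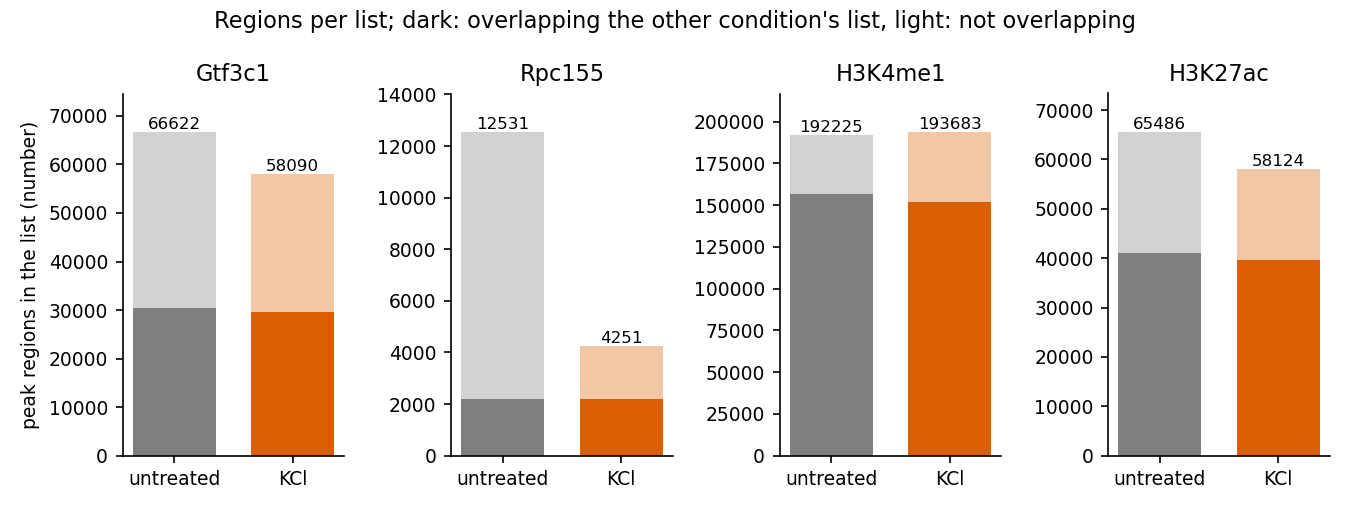
Number of peak regions in each list (y axis, a separate scale per antibody) for untreated (grey) and KCl-treated (orange) neurons; the dark part overlaps the other condition's list by at least 1 bp and the light part does not. The Rpc155 list goes from 12531 to 4251 regions, while H3K4me1 stays near 193683.

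Of the 10 strongest Rpc155 regions, 8 in the untreated list lay at tRNA genes, and in the KCl list 9 did, the other lying at Rmrp, which encodes the RNA component of RNase MRP. The first region of the untreated list (chromosome 6, 47748019 to 47748803, fold enrichment 43.7) lay next to a predicted noncoding gene, and the fifth was 14287 bp from Klrb1c, a natural killer cell receptor gene. The KCl list was led by a region at chromosome 11, 69040055 to 69042050, next to the tRNA gene n-TGtcc6, with a fold enrichment of 64.7. The untreated list included a region of fold enrichment 62.3 at n-TEctc10 (chromosome 11, 58301297 to 58303117). The 10 strongest Gtf3c1 regions of each list were elsewhere. In untreated neurons they included Itprip, which encodes an inositol trisphosphate receptor-interacting protein (chromosome 19, 47919045 to 47919910, fold enrichment 46.7), Rnf44 (chromosome 13, 54692639 to 54694714, 44.4) and Nfix, a nuclear factor I gene of neural development (chromosome 8, 84770814 to 84776162, 38.9). With KCl, Itprip and Nfix were again among the 10 strongest, joined by Mdga1, which encodes a cell adhesion protein, and Pip5k1c, which encodes a lipid kinase. Among the 10 strongest Rpc155 regions of the KCl list alone, by q, those with a summit inside a named protein-coding gene lay, in order, in Grk5, a receptor kinase gene (chromosome 19, 60890836 to 60891295, 12.2), Sez6l2, a neuronal surface protein gene, Myt1l, a neuronal zinc finger gene, Adamts6, a metalloprotease gene, Tmem74, an autophagy gene, Adgrl3, which encodes latrophilin 3, Mapk10, which encodes the kinase JNK3, and Sik1, which encodes a salt-inducible kinase (chromosome 17, 31854453 to 31855173, 8.90). Those of Gtf3c1 lay, in order, in Igfbp2, which encodes a growth factor-binding protein (chromosome 1, 72825566 to 72826174, 13.99), Sox6, a transcription factor gene of interneurons, Crem, a cAMP-responsive and activity-regulated gene, Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, Frmpd4, which encodes a postsynaptic scaffold protein, Bcl6, a repressor gene of cortical neurogenesis, and Efnb1, which encodes an ephrin. The Lars2 region ranked by its −log10 q of 42.8 but had a fold enrichment of only 3.28, where the others had 10.2 or more. The H3K27ac regions of the KCl list alone included Taf8, which encodes a TFIID subunit (chromosome 17, 47501498 to 47502709, 12.6), Prox1, a homeobox gene of the dentate gyrus, and the immediate-early gene Egr2. Those of H3K4me1 included Hsph1, which encodes a heat shock protein, and Crebbp, which encodes the acetyltransferase CBP.

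Genes transcribed by RNA polymerase III served as a positive control for the antibodies, not as a check on their specificity. Of 408 nuclear tRNA genes, 267 (65.4%, 60.6 to 70.1) had an Rpc155 region in untreated neurons and 253 (62.0%, 57.1 to 66.7) with KCl, where random placement gave 1.85 and 0.58. Gtf3c1 was listed at 225 and 226 tRNA genes, against 9.83 and 8.95 at random. The median fold enrichment of Rpc155 at tRNA genes was 39.3 in the untreated and 40.0 in the KCl list, and 3.57 and 3.63 elsewhere. tRNA genes thus made up 1.52% of the untreated and 4.28% of the KCl regions of Rpc155. H3K27ac was listed at 159 tRNA genes in untreated neurons and at 205 with KCl, and H3K4me1 at 128 and 153.

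Of the 10 other RNA polymerase III genes examined, 9 had an Rpc155 region in both lists: Rn7sk, Rn7s1, Rn7s2, Rmrp, Rpph1, Rny1, Rny3, Vaultrc5 and Bc1. Rmrp (chromosome 4, 43492785 to 43493059) had fold enrichments of 58.2 and 60.5, and Bc1, a dendritic RNA of neurons (chromosome 7, 144914470 to 144914623), 17.5 and 16.7. Rn7sk, whose RNA restrains the elongation factor P-TEFb, had 47.7 in the untreated and 32.9 in the KCl list. Gtf3c1 was found at 8 of the 10 genes in untreated neurons and at 9 with KCl, Bc1 being listed with KCl only. Gtf3c1 was thus listed in both conditions also at Rn7sk, Rmrp, Rpph1, Rny1 and Rny3. Genes of different promoter types were not separated here, so this count is not a check on the specificity of the Gtf3c1 antibody. Rnu6 had no region of Gtf3c1, Rpc155 or H3K27ac, and none of the 53 5S rRNA genes had a region in any of the 8 lists. Both belong to repeated families, at which the lists cannot separate lack of binding from lack of uniquely placed reads.

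The next comparison asked whether Gtf3c1 and RNA polymerase III coincided with each other and with the histone marks. Rpc155 regions overlapped a Gtf3c1 region in 76.3% of cases (75.5 to 77.0) in untreated neurons and in 81.8% (80.6 to 83.0) with KCl, 29.7 and 35.6 times the random share. With equal numbers of regions the order turned, at 86.5% and 81.8%. Seen from Gtf3c1, 14.3% of regions overlapped Rpc155 in the untreated and 5.88% in the KCl lists, or 6.48% and 5.88% with equal numbers of regions. H3K27ac overlapped 80.6% of Rpc155 regions in untreated neurons and 87.3% with KCl, against 4.12% and 4.01% at random. It overlapped 48.9% of Gtf3c1 regions in untreated neurons and 51.6% with KCl. H3K4me1 overlapped 74.9% and 70.4% of Gtf3c1 regions, and 83.1% and 86.4% of Rpc155 regions. When the regions were moved only 10 to 100 kb, the observed shares were 14.99 and 13.7 times the random share for Rpc155 in Gtf3c1 and 5.36 and 4.79 times for Gtf3c1 in H3K27ac.

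**Figure D2:**
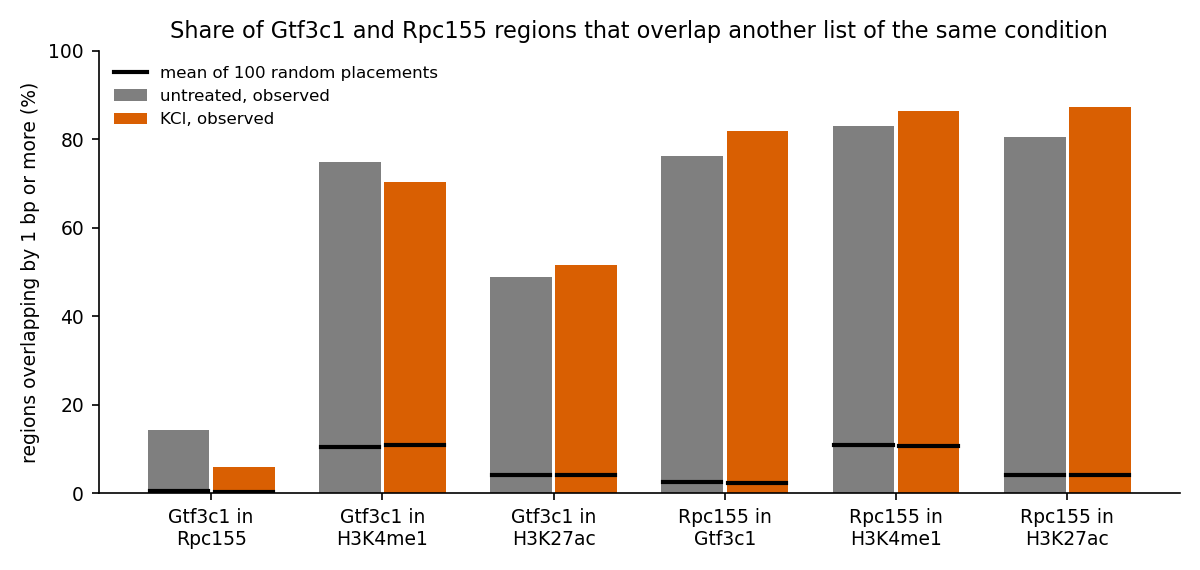
Share of Gtf3c1 and Rpc155 regions (y axis, %) that overlap a region of another antibody in untreated (grey) and KCl-treated (orange) neurons; black lines mark the mean of 100 random placements. Rpc155 in H3K27ac stands at 80.6% and 87.3%, against 4.12% and 4.01% for placed regions.

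By their summits, 38.8% of Rpc155 regions (37.97 to 39.7) lay within 1 kb of a gene end in untreated neurons and 44.8% (43.3 to 46.3) with KCl, against 6.44% at random. For Gtf3c1 the shares were 20.6% and 23.0%, for H3K27ac 20.6% and 23.8%, and for H3K4me1 12.2% and 12.04%. Gtf3c1 regions outside genes made up 21.8% of the untreated and 14.7% of the KCl list. Gtf3c1 regions of the KCl list alone lay inside genes, more than 1 kb from their ends, in 74.3% of cases, against 50.8% of those that overlapped an untreated region. The same shares for the untreated list of Gtf3c1 were 63.2% and 50.9%. For Rpc155 they were 38.3% and 32.2% in the KCl list and 37.7% and 32.4% in the untreated list.

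Active distal enhancers numbered 39651 in untreated neurons and 34873 with KCl. Gtf3c1 was listed at 18060 of them (45.5%, 45.1 to 46.0) in untreated neurons and at 13136 (37.7%, 37.2 to 38.2) with KCl. Rpc155 was listed at 4743 (11.96%, 11.6 to 12.3) and 1497 (4.29%, 4.08 to 4.51), and both factors at 4120 and 1321. With equal numbers of regions Rpc155 was at 1643 (4.50%) and 1497 (4.30%) enhancers, and both factors at 1517 and 1321. Seen from the factors, 34.3% of untreated and 30.7% of KCl regions of Gtf3c1 lay at such enhancers, against 3.31% and 3.20% at random. For Rpc155 the shares were 40.3% and 36.1%, against 3.39% and 3.20%. Rpc155 regions of the KCl list alone lay at active distal enhancers in 35.6% of cases (33.5 to 37.7), and those shared with the untreated list in 36.6% (34.6 to 38.7). For Gtf3c1 the shares were 23.7% and 37.5%, and for H3K27ac 58.4% and 67.9%. In the untreated lists, regions of that list alone and shared regions stood at 41.2% and 36.5% for Rpc155. They stood at 31.9% and 37.1% for Gtf3c1 and at 66.4% and 64.6% for H3K27ac. At a q of 1e-05 or lower the KCl shares were 34.3% and 24.8% for Rpc155, 24.7% and 30.8% for Gtf3c1, and 61.2% and 59.9% for H3K27ac.

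Near the 52 immediate-early and delayed activity-regulated genes, within 50 kb, there were 146 active distal enhancers in untreated neurons and 199 with KCl. Gtf3c1 was listed at 71 (48.6%) and 95 (47.7%) of them, and Rpc155 at 17 (11.6%, 6.93 to 18.0) and 20 (10.1%, 6.25 to 15.1). Across all active distal enhancers the Rpc155 shares were 11.96% and 4.29%, as given above, and their difference went with the length of the Rpc155 lists.

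The comparison at the centre of the design was that of genes induced by neuronal activity. Among 32 immediate-early genes, Rpc155 was listed within 5 kb of a gene end at 17 in untreated neurons and at 19 with KCl, although its regions near all protein-coding genes covered 6255 genes in the untreated and 2599 in the KCl list. With equal numbers of regions the counts over all protein-coding genes were 2368 and 2599, and at a fold enrichment of at least 6 the untreated count was 292 and the KCl count larger by 10. The 5 genes with Rpc155 in the KCl list alone were Fos and Junb, which encode AP-1 subunits, the transcription factor gene Egr4, and the growth arrest genes Gadd45b and Gadd45g. Arc, which encodes a synaptic scaffold protein, Maff and Csrnp1 had Rpc155 in the untreated list alone. The other 14 included Fosb, Egr1, Npas4, Nr4a3 and Sik1 and had it in both. The net gain of 2 lay at percentile 99.8 of random gene lists, whose mean was −5.05 with 95% of lists between −10 and 0. With equal numbers of regions the counts were 5 and 19, and at a q of 1e-05 or lower 4 and 12; within 50 kb they were 25 and 23, a net loss of 2 at percentile 98.6. At a fold enrichment of at least 6 only 3 and 4 genes had an Rpc155 region, with the net gain at percentile 95.2.

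Gtf3c1 was near 31 of the 32 immediate-early genes in untreated neurons and all 32 with KCl, Dusp5 being the addition. The regions differed in strength and width, which were looked at after the lists had been seen. At a fold enrichment of at least 6, Gtf3c1 was near 8 genes in the untreated list and 26 in the KCl list, and no gene was in the untreated list alone. The net gain of 18 lay at percentile 100, where random lists averaged 1.34. Over all protein-coding genes the counts at this fold enrichment were 2015 and 2836. The 18 genes included Egr1, Nr4a1, Npas4, Jun, Srf and Sik1. At Sik1 the strongest Gtf3c1 region had a fold enrichment of 4.66 in the untreated list and 25.3 in the KCl list (chromosome 17, 31852390 to 31856915). At Egr1, a zinc finger transcription factor gene, the values were 4.30 and 16.7. Gtf3c1 regions covered on average 19.02% of the length of the 32 genes in untreated neurons and 63.1% with KCl, with a larger share in 31 genes and a smaller one in 1; over all protein-coding genes the mean shares were 4.21% and 4.88%. Rpc155 regions covered 3.00% and 5.29% of the 32 genes, larger in 14 and smaller in 6.

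H3K27ac was listed near 31 immediate-early genes in untreated neurons and near all 32 with KCl, Egr2 being the addition, a net gain at percentile 47.0. At a fold enrichment of at least 6 the counts were 17 and 32, a net gain of 15 at percentile 100, where random lists averaged 4.42 and the counts over all protein-coding genes were 7057 and 10279. The 15 genes included Arc, Junb, Btg2, Atf3 and Ccn1. H3K4me1 was near all 32 genes in both lists. At Fos (chromosome 12, 85473890 to 85477274) a single Gtf3c1 region spanned 85473325 to 85479707 with KCl, where the untreated list had 85473385 to 85474279 at its lower-coordinate end and a weaker region inside it at 85474529 to 85474765 (fold enrichment 2.87). Rpc155 was listed at 85473838 to 85474439 (fold enrichment 2.43) and at 85476927 to 85477548 (4.36) with KCl and at neither in untreated neurons. The first of these had a −log10 q of 1.49, close to the lowest of the KCl Rpc155 list, 1.46. Around Fos, 3 distal places carried Gtf3c1 and Rpc155 in both conditions, with KCl Rpc155 regions at 85435471 to 85437320, 85455571 to 85456348 and 85487326 to 85488850.

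**Figure D3:**
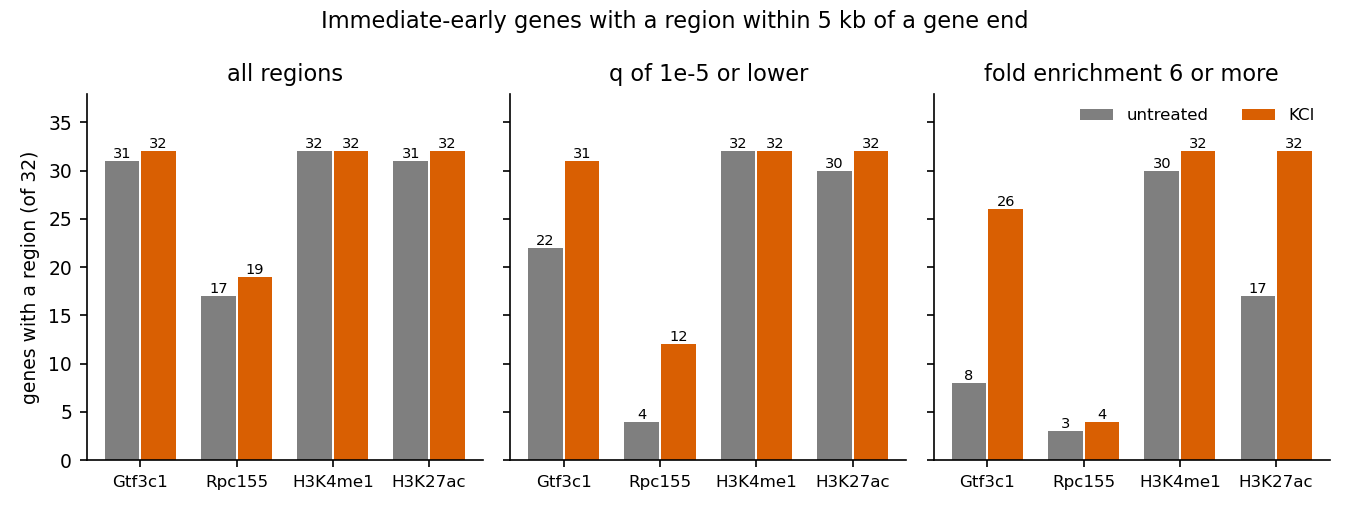
Number of the 32 immediate-early genes (y axis) with a region of each antibody within 5 kb of a gene end, untreated (grey) and KCl (orange), for all regions, for a q of 1e-5 or lower and for a fold enrichment of 6 or more. Gtf3c1 goes from 8 to 26 genes and H3K27ac from 17 to 32 in the last panel.

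**Figure D4:**
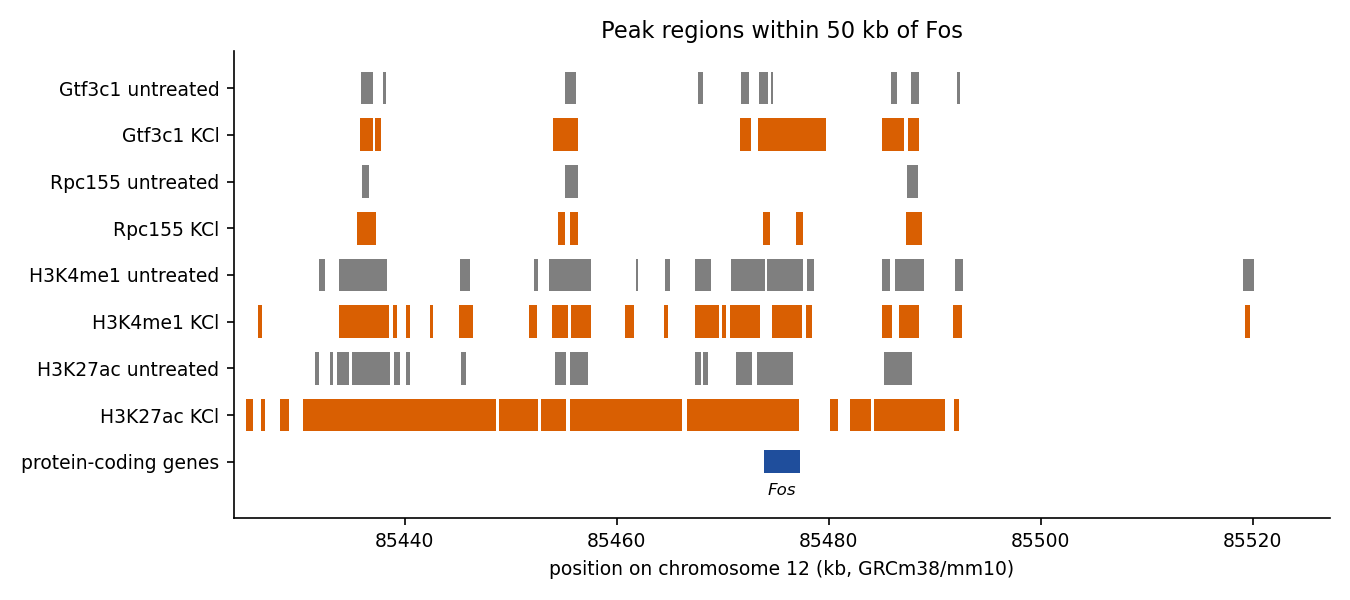
Peak regions of the 8 lists within 50 kb of Fos on chromosome 12 (x axis, kb, GRCm38/mm10), untreated in grey and KCl in orange, with Fos in blue. Rpc155 has 3 regions in untreated neurons and 6 with KCl, and the Gtf3c1 region over Fos is wider with KCl. The untreated Rpc155 region at 85455099 to 85456333 overlaps separate KCl regions at 85454432 to 85455106 and 85455571 to 85456348. The KCl region at 85473838 to 85474439 has a −log10 q of only 1.49.

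Of 20 delayed activity-regulated genes, 7 had an Rpc155 region in each list. With equal numbers of regions 0 and 7 had one (percentile 99.985), at a q of 1e-05 or lower 0 and 2 (percentile 99.2), and at a fold enrichment of at least 6 none in either list. Rgs2, Scg2 and Plk3 had one in the KCl list alone, and Bdnf, which encodes a neurotrophin, Grasp and Mmp9 in the untreated list alone. Gtf3c1 was near 14 and 16 of these genes, with Pcsk1, Ptgs2 and Rasgrp1 in the KCl list alone and Nptx2 in the untreated list alone. H3K27ac was near 18 and 19, Ptgs2 being the addition, and H3K4me1 near 19 and 20, with Inhba. The net values of these genes lay at percentile 95.6 for Rpc155 and 90.7 for Gtf3c1. For Rpc155 the net value was 0 and random lists averaged −3.59, so the rank marks absence of a net loss, not a gain.

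Genes of the RNA polymerase III machinery were compared in the same way. Rpc155 was listed near 21 of these 28 genes in untreated neurons and 5 with KCl, at percentile 0 of random lists. At a q of 1e-05 or lower the counts were 8 and 1, and at a fold enrichment of at least 6 only Polr3e had a region, in both lists. Brf1, Maf1, Polr3a and 15 others had a region in the untreated list alone, Gtf3c1 and Polr3c in the KCl list alone, and Polr3e, Polr3gl and Tbp in both. Among random lists matched also on H3K27ac the percentile was 0.415. Neither set of random lists was matched on the number of genes with an untreated Rpc155 region. A list with many such genes has more to lose to the shorter KCl list, so the percentile overstates the difference. Of 21 machinery genes with an untreated region 3 had one in both lists, against 1831 of 6255 protein-coding genes. Gtf3c1 was near all 28 and 24 of them, at percentile 2.16, but near 18 and 21 at a q of 1e-05 or lower and near 1 and 5 at a fold enrichment of at least 6. Of 12 housekeeping genes, 9 had Rpc155 in the untreated list and 4 in the KCl list, Gapdh, Ppia, Sdha, B2m and Rplp0 being in the untreated list alone. This lay at percentile 3.97, at the edge of the random range of −5 to 1, and at 18.4 among lists matched also on H3K27ac. The same limit holds here: 4 of the 9 genes had a region in both lists, a share no lower than over all protein-coding genes. Of 24 synaptic genes, 13 had Rpc155 in each list, with Snap25, Syt1, Grin2b and Map2 in the KCl list alone and Syn2, Grin1, Shank1 and Camk2b in the untreated list alone. Their net value of 0 lay at percentile 97.2, and at 98.9 among lists matched also on H3K27ac. Since random lists lost genes on average, this rank marks absence of a net loss, not a gain. Microglial and non-neural genes, with no Rpc155 region in either list, ranked at 83.6 and 84.4. At a fold enrichment of at least 6, Rpc155 was near synaptic genes that included Gria1, Rbfox3 and Gap43 in both lists, and near Nlgn1 and Map2 in the KCl list alone. Of 11 glutamatergic genes, 8 had Rpc155 in the untreated list and 4 in the KCl list, at percentile 11.1 and inside the random range of −5 to 1.

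H3K27ac at marker genes described the cells in culture. All 11 glutamatergic genes, among them Slc17a7 and Tbr1, had an H3K27ac region within 1 kb of a gene end in both conditions. Of 10 GABAergic genes, 9 had one in untreated neurons and 10 with KCl, the neuropeptide gene Sst being the addition. Of 24 synaptic genes, 23 had one in each list. Astrocyte genes had a region at 6 of 9 in untreated neurons and at 5 with KCl, among them Gfap and Slc1a3. Progenitor genes had one at 4 of 7 and at 6, Nes and Eomes being in the KCl list alone. Oligodendrocyte-lineage genes had one at 1 of 8 in both lists (Mbp), endothelial genes at 1 of 6 (Cdh5 untreated and Flt1 with KCl) and non-neural genes at 1 of 10 (Acta1). Of 7 microglial genes, Trem2 had one in the untreated list, and the KCl list had 0. Housekeeping genes had one at 11 of 12 and at all 12. Within 5 kb, a wider window, 13018 of 21887 protein-coding genes had one in the untreated list and 13831 with KCl. Against this background the astrocyte and progenitor counts say little about which cells were present.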

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

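Each antibody and condition has 1 list, so leaving out a replicate was not possible, and library-to-library variation could not be judged. The search for SINE sequences and its 400 bp window were not run, since no genome sequence was used here. Depth limits the weaker regions most. The ratio of the KCl to the untreated background was 0.922 for Rpc155 and 0.931 for H3K27ac, so regions just past the threshold are the least certain. A count was called changed when it differed by more than 1.5 times, a share when it left the 95% interval of the main value.

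Among the net changes at immediate-early and delayed activity-regulated genes, the sign was reversed in 1 result. Within 50 kb in place of 5 kb, the net change of Rpc155 at immediate-early genes was −2 in place of 2, and that of H3K27ac was 0 in place of 1. The wider window also takes in regions of neighbouring genes, and the KCl list of Rpc155 was the shorter across the genome. Outside these gene lists other signs turned as well. Over all protein-coding genes the net change of Gtf3c1 was −154 in the full lists and 230 at a q of 1e-05 or lower. That of Rpc155 was −3656, and 231 with equal list lengths. At RNA polymerase III machinery genes Gtf3c1 turned from 28 and 24 genes to 18 and 21 at the stricter q.

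At a q of 1e-05 or lower, the lists held 32815 untreated and 25365 KCl regions of Gtf3c1, 3390 and 1528 of Rpc155, and 35047 and 30116 of H3K27ac. The untreated share also found with KCl was 46.7% for Gtf3c1, 25.2% for Rpc155, 83.6% for H3K4me1 and 70.3% for H3K27ac. Rpc155 had 2535 regions in the untreated list alone and 668 in the KCl list alone. Gtf3c1 lay in H3K27ac in 51.6% of untreated and 60.5% of KCl regions, and Rpc155 in Gtf3c1 in 82.0% and 89.5%. At active distal enhancers the shares were 31.2% and 28.3% for Gtf3c1 and 32.8% and 28.9% for Rpc155. Within 1 kb of a gene end they were 22.5% and 30.8% for Gtf3c1 and 40.7% and 46.4% for Rpc155. The net gain at immediate-early genes was 9 for Gtf3c1, 8 for Rpc155 and 2 for H3K27ac.

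With equal list lengths, the shared share was 48.9% for Gtf3c1, 32.6% for Rpc155, 81.4% for H3K4me1 and 67.2% for H3K27ac, with 2865 Rpc155 regions in the untreated list alone. Untreated Gtf3c1 lay in H3K27ac in 50.2% of cases, Rpc155 in Gtf3c1 in 86.5%, and Rpc155 at enhancers in 38.1%. The KCl share of Rpc155 in Gtf3c1 stayed at 81.8%, so the untreated share became the higher of the pair. The net gain at immediate-early genes was 2 for Gtf3c1 and 14 for Rpc155. The larger Rpc155 gain follows in part from construction, since only the untreated list was shortened.

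With an overlap of at least 50% of the shorter region, the shared share was 41.7% for Gtf3c1, 15.5% for Rpc155, 78.3% for H3K4me1 and 57.8% for H3K27ac. Gtf3c1 lay in H3K27ac in 39.5% and 45.9% of regions, and Rpc155 in Gtf3c1 in 67.3% and 72.9%. The shares at enhancers were 29.6% and 26.8% for Gtf3c1 and 36.3% and 33.2% for Rpc155. All are lower, as a stricter overlap must give.

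Placing regions 10 to 100 kb away lowered the ratio to random to 5.36 and 4.79 for Gtf3c1 in H3K27ac and to 14.99 and 13.7 for Rpc155 in Gtf3c1, so that the untreated ratio became the higher in each pair. A distal limit of 5 kb gave 25.9% and 21.3% of Gtf3c1 and 31.1% and 25.5% of Rpc155 regions at enhancers. The whole region in place of the summit put 23.3% and 26.0% of Gtf3c1 and 41.4% and 48.1% of Rpc155 regions within 1 kb of a gene end. Within 5 kb, microglial genes with H3K27ac numbered 2 and 2 (Aif1 and Trem2), oligodendrocyte-lineage genes 3 and 3 (Cspg4, Mbp and Mog) and non-neural genes 1 and 3 (Hba-a1 and Cdx2 being added). Astrocyte genes numbered 6 and 7, in place of 6 and 5.

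A fold enrichment of at least 6 was added after the data were seen. It left 7921 and 5532 regions of Gtf3c1, 588 and 584 of Rpc155, 48194 and 52233 of H3K4me1, and 8321 and 11271 of H3K27ac, where the KCl list became the longer. The shared share was 43.2% for Gtf3c1, 65.1% for Rpc155 and 86.8% for H3K27ac, with 205 Rpc155 regions in the untreated and 196 in the KCl list alone. The net gain at immediate-early genes was 18 for Gtf3c1, 1 for Rpc155, 2 for H3K4me1 and 15 for H3K27ac, and the Rpc155 percentile was 95.2. The difference in length of the Rpc155 lists thus lay among regions below this fold enrichment.

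Joining regions under 1 kb apart, the deposited regions unmerged, and the same p in both lists left all 8 region counts within 1.5 times of the main ones. Matching random lists also on H3K27ac cannot change a net count, only its percentile. At immediate-early genes the percentile was 99.96 in place of 99.8 for Rpc155. For H3K27ac it was 90.1 in place of 47.0, which follows largely from construction. Random genes matched on having an H3K27ac region in both lists can show no net change of H3K27ac. Their lists averaged 0.159 in place of 1.18. Outside the values printed here, the q threshold changed 20 results and left 2, equal lengths changed 8 and left 14, the 50% overlap changed 12 and left 6, and a fold enrichment of 6 changed 12 and left 2. Local placement changed 8, the 5 kb marker window changed 3 and left 11, and the 50 kb window changed 2 and left 2. Where construction does not give the reason, the cause was not tested.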

Other observations

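The tests of depth and of a neighbouring tRNA gene were set before their results were seen. The other 6 were chosen after the result was seen: the cutoff, enrichment at all sites, gene body signal, acetylated chromatin, reads lost at tRNA genes, and Gtf3c1 without RNA polymerase III.

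The strongest class of Rpc155 regions lay mostly at known RNA polymerase III genes. Of 177 untreated regions with a fold enrichment of at least 20, 154 lay at an annotated tRNA or other RNA polymerase III gene, and of 189 KCl regions 148 did. Between fold enrichments of 6 and 10, only 21 of 323 untreated and 15 of 241 KCl regions did. The places of the strongest class elsewhere numbered 23 and 41. Near Klrb1c, a natural killer cell receptor gene, such a region reached 61.0 in untreated neurons (chromosome 6, 128763744 to 128764556). Below a fold enrichment of 6, 10 of 11943 untreated and 8 of 3667 KCl regions lay at these genes.

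Chromosome X held few regions of every antibody. It makes up 6.31% of the span used here, but held 15 (0.120%) of the untreated and 16 (0.376%) of the KCl regions of Rpc155. The shares of H3K27ac were 1.09% and 1.28%. Chromosome 19, with 2.15% of the span, held 342 and 146 Rpc155 regions. The cause was not tested.

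The Rpc155 list was 2.95 times shorter with KCl. Lower depth of the KCl library would thin the untreated list to a similar length, but thinning it to 92.2% of the background left 11609 regions (11554 to 11659 over 21 draws), 2.73 times the KCl list, so depth as read from the background does not account for it (10654 if the kept share was 86.8%). A stricter cutoff does not either, with 12174 untreated regions at the same p, and the tRNA median fold enrichment was no lower with KCl, at 40.0 against 39.3. At the other RNA polymerase III genes the median was lower, 32.9 with KCl and 43.1 without. The medians cover only regions that were in each list, 190 untreated and 182 KCl regions at tRNA genes. No lower enrichment was seen at listed tRNA genes, but a lower enrichment is not excluded, least of all at weaker sites. Loss of weak RNA polymerase III binding on depolarization remains untested, as does variation between libraries, which 1 list per condition cannot show.

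In the full lists, immediate-early genes had a net gain of Rpc155 regions of 2 within 5 kb, while all protein-coding genes had a net loss, which was absent with equal list lengths (2368 and 2599 genes). A tRNA gene next to the gained genes was not the source, with 0 of 5 having one within 5 kb. Lists matched on the H3K27ac fold enrichment of the KCl list seldom reached such a gain, the list lying at percentile 99.965 (random mean −9.37). This speaks only to the level of acetylation. The match was not on its change with KCl, so a gain of acetylation stays open. The test also used the full Rpc155 lists, which differ in length. Signal spread over strongly transcribed gene bodies could give the Rpc155 gain. The change in covered gene length lay at percentile 99.99 for Rpc155, and Gtf3c1 and H3K27ac cover was larger with KCl in 31 genes each. Recruitment of TFIIIC and RNA polymerase III by depolarization would predict the same cover, so the test does not separate them. A library from an antibody unrelated to transcription, or the input at these genes, could do so and was not analysed here. The share of gene length covered by H3K4me1 was not computed. At a fold enrichment of at least 6, H3K4me1 was near 30 and 32 of the 32 genes (percentile 69.3). Nearly all genes had it in both lists, so this count cannot decide.

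Most of the strongest Gtf3c1 regions lay away from tRNA genes. Of the top 500, 7 (1.40%) untreated and 21 (4.20%) KCl regions overlapped one, against 178 (35.6%) and 171 (34.2%) for Rpc155. Still, tRNA genes were more frequent there than in the full Gtf3c1 lists, at 0.248% and 0.281% of regions. The median Gtf3c1 fold enrichment was 9.31 and 10.8 at tRNA genes, and 3.58 and 3.52 elsewhere. Loss of reads at repeated tRNA genes was looked at where reads were kept. Of 220 tRNA genes under an untreated Rpc155 region of fold enrichment 20 or more, 210 had a Gtf3c1 region. Reads were thus not wholly lost there, though a partial loss is not excluded. Only 14 (6.36%) had one of the top 500, but this restates the pattern, since only 7 of the top 500 lay at tRNA genes. The 141 tRNA genes with no Rpc155 region stay open. Gtf3c1 bound without RNA polymerase III does not describe most of the strongest Gtf3c1 regions. Of the untreated top 500, 78.8% overlapped Rpc155, at a median Rpc155 fold enrichment of 5.77. Binding of the antibody to another protein could give the same picture and was not tested.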
